A study of Caenorhabditis elegans with 2 samples.

How the data were processed

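The data come from ChIP-seq of C. elegans strain RJP5356, in which dmd-6 was tagged by CRISPR with GFP, an auxin-inducible degron and a FLAG epitope. Per the labels, synchronised L4 larvae (48 hours) were collected whole in 2 biological replicates of 1 group, chromatin was sonicated, and the immunoprecipitation used an antibody against GFP (a separate label field gives the antibody as dmd-6). Replicate numbers were taken from the labels. The labels also name a control experiment, which was not used here.

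The processed files are 8 peak lists on the assembly ce11, per the labels and the file headers: a thresholded and a ranked list for each replicate, and 2 thresholded and 2 ranked lists called on both replicates together. The descriptions that accompany the lists name the output types and, as sources of each list, alignments and a further file; companion tracks are described there as fold change over control. The aligner, the peak caller and their versions are not given in the sources used here. IDR, the irreproducible discovery rate, measures how well the ranks of peaks hold between replicates or between random parts of the reads. The deposited score is the authors' peak score, which in each thresholded list starts at 830 and reaches 1000. The deposited signal is the authors' value for each peak, on a scale of its own in each list and with a formula that is not given in the sources used here, so it served to rank peaks within a list and for rank correlation between the replicates. The deposited ranked lists give the −log10 of the global IDR, by the layout that the authors name. The summit is an offset in bp from the start of the peak. Each thresholded list was tested against a ranked list and was found to hold peaks with a −log10 IDR of at least 2 (IDR of 0.01) and no others, but 32 to 45 passing peaks were left out of each. The descriptions of the thresholded lists name 1 more input than those of the ranked lists, and its nature is not given in the sources used here. Each ranked list also has 8 columns on the compared replicates or read parts, which were not used because nothing names which is which.

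The main list was the larger thresholded list called on both replicates, with 7338 peaks; a peak interval with more than 1 summit is given once per summit. The depth in reads is unknown, so nothing that needs it was computed. All intervals are exact binomial intervals at 95% unless stated, and they and the p-values cover counting of peaks, genes or windows only. Gene models came from Ensembl release 115 and the sequence from the RefSeq copy of the same assembly, WBcel235.

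Replicate overlap counted peaks that overlap by at least 1 bp, against 1000 random circular shifts within each chromosome (one-sided permutation test). Signals were compared by Spearman's rho over overlapping pairs, with an approximate interval from Fisher's transformation. Promoter summits lay from 500 bp upstream to 100 bp downstream of a start site of any gene, and other summits were assigned in the order 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. Chromosome counts were tested with a chi-square test against length. A protein-coding gene had a peak when a summit lay from 1000 bp upstream to 200 bp downstream of any of its start sites. The 31 gene lists were tested with a two-sided Fisher's exact test against all protein-coding genes on nuclear chromosomes with Benjamini-Hochberg adjustment; log2 odds ratios had 0.5 added to each cell. The 16 sequence words were counted on both strands in 101-bp windows at the summit and 350 bp to its left and compared with a two-sided exact McNemar test, adjusted over the words. W stands for A or T and S for C or G. The search over 7-mers used a one-sided Fisher's exact test against both flanks, with discovery on chromosomes I, II and III and a test of the leading 10 on IV, V and X. These tests, the lists, the words and the alternatives were fixed before the data were examined, except where a choice is said to be made after seeing the data.

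The genes named were chosen by a rule fixed beforehand: dmd-6 and the DM-domain genes with a peak; the protein-coding gene with the nearest start site among those whose gene window held the summit, for the 15 strongest peaks overlapping both replicates, with peaks outside any such window given by position and annotation; up to 4 members with the strongest peak of each list past an adjusted p of 0.05; and at most 1 member of each other list. Other genes are named only as sharing a peak, or, like the neighbours irld-18 and 21ur-865 of the strongest peak, were chosen after the values were seen.

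The functions were tested on simulated data. With 53.7% of 7338 simulated summits in promoters, 54.8% were recovered; at random positions the promoter share was 1.03 times the shifted one; of simulated replicate peaks made to overlap in 70.0%, 71.0% were found. A planted gene list was called and 0 of 10 random lists were, and 0 of 16 words were called at random positions. A DM word planted in 10% of windows at random positions raised the share by 9.83 percentage points and was called, as it was when planted in 1%.

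Alternatives covered the overlap rule, the conservative list, the 1000 strongest peaks, each replicate alone, other promoter windows, gene sets, backgrounds, assignment to the nearest start site, merged summits, control windows and the reversed chromosome split. Peaks found in both replicates and peaks away from tRNA genes were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.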

Results

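The data describe where a GFP-tagged DMD-6 protein was found on the genome of the nematode Caenorhabditis elegans. DMD-6 belongs to the DM-domain family of DNA-binding proteins, the family of Drosophila Doublesex and worm MAB-3, which is known for its part in sex determination. The worms carried a CRISPR insertion of GFP, a degron and epitope tags in dmd-6 itself, so that the protein was made from its own locus. They were synchronised by starvation at the first larval stage and were collected whole as L4 larvae, the last larval stage, at 48 hours. Chromatin was immunoprecipitated with an antibody against GFP and sequenced, an assay called ChIP-seq. The series holds 1 group with 2 biological replicates and no second condition. The comparisons are therefore those between the replicates and those between the peaks and the genome around them. With 2 samples no test across samples can be made, so each p-value and interval below covers the counting of peaks, genes or windows within a list. Read numbers are not used here and the sequencing depth is unknown; the number of peaks is the only measure of yield.

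The first comparison asked how far the replicates found the same sites. Replicate 1 held 6533 peaks and replicate 2 held 4653, and the strongest sites were nearly all shared. Of the replicate 2 peaks, 90.9% (4229; 95% exact binomial interval 90.02 to 91.7%) overlapped a replicate 1 peak by at least 1 bp, against 3.66% on average when the list was shifted along the chromosomes. Of the replicate 1 peaks, 64.9% (4238; interval 63.7 to 66.0%) overlapped a replicate 2 peak, against 2.61% after shifting. Both shares gave p = 0.000999 in a one-sided permutation test, the smallest value that 1000 shifts can give. The 2295 replicate 1 peaks without a partner were weaker, with a median signal of 65.1 against 128.0 for the shared ones, where signal is the authors' value for each peak, by a formula not given in the sources used here. Nearly all of the replicate 1 peaks (94.7%) and replicate 2 peaks (97.7%) overlapped an entry of the other replicate's full ranked list, in which peaks are kept before any reproducibility threshold. The ranked lists cover more of the genome, 7.92% in replicate 1 and 8.90% in replicate 2, against 1.80% and 1.27% for the thresholded lists. More of this overlap is therefore due to position alone than the shifted shares above. Of the 500 strongest peaks of replicate 1, 391 overlapped one of the 500 strongest of replicate 2, and 498 overlapped some thresholded peak of replicate 2. Over the 4147 matched pairs the signals of the replicates rose together, with a Spearman rho of 0.833 across peaks (approximate 95% interval 0.822 to 0.842); peaks are not independent replicates, so no p is given.

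**Figure D1:**
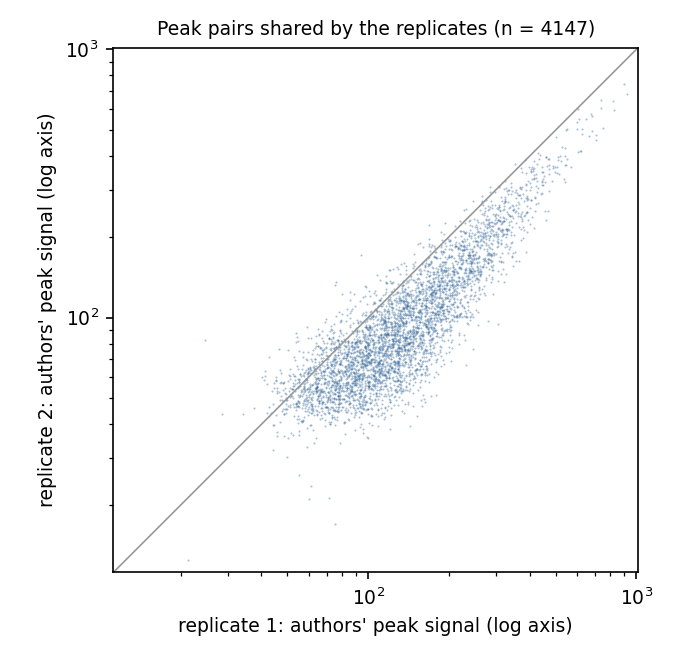
Each point is 1 of the 4147 pairs of overlapping peaks, with the authors' peak signal in replicate 1 on the x axis and in replicate 2 on the y axis, both logarithmic, and a grey line where the values are equal. The points follow a single rising band (Spearman rho 0.833), with medians of 129.5 in replicate 1 and 85.3 in replicate 2.

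The main list, called on both replicates together, held 7338 peaks with a median width of 344 bp that covered 2.07% of the genome. The conservative list held 6626 peaks. The ratio of the replicates' peak numbers (self-consistency ratio) was 1.4, and that of the 2 series lists (rescue ratio) was 1.11. Of the 7338 peaks, 4293 (58.5%) overlapped a thresholded peak of both replicates, 1917 of replicate 1 only, 295 of replicate 2 only and 833 of neither. The peaks found in both were the stronger ones, with a median signal of 208.4 against 73.96 for those found in neither. In the fifth of peaks with the highest signal, 99.5% were found in both, and in the fifth with the lowest signal 12.1%.

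Peaks lay at promoter windows more often than after shifting and avoided coding sequence. Of the 7338 summits, 52.1% (3821; exact interval 50.9 to 53.2%) fell from 500 bp upstream to 100 bp downstream of an annotated transcription start site, 2.32 times the 22.5% found after shifting (p = 0.000999, one-sided permutation test with 1000 shifts). Coding exons held 3.67% of the summits against 20.7% after shifting, and introns 15.9% against 28.8%. Intergenic sequence outside the promoter windows held 25.6%, against 22.8% after shifting. The median distance from a summit to the nearest start site of a protein-coding gene was 709 bp. Annotated 5′ ends of worm genes are often sites of trans-splicing rather than of transcription initiation, and genes inside operons lack promoters of their own, so the promoter share depends on the annotation. The windows also include the start sites of non-coding genes, among them 15363 piRNA genes and 7764 genes annotated as ncRNA. With start sites of protein-coding genes alone the share was 39.2%, 2.79 times the shifted level.

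**Figure D2:**
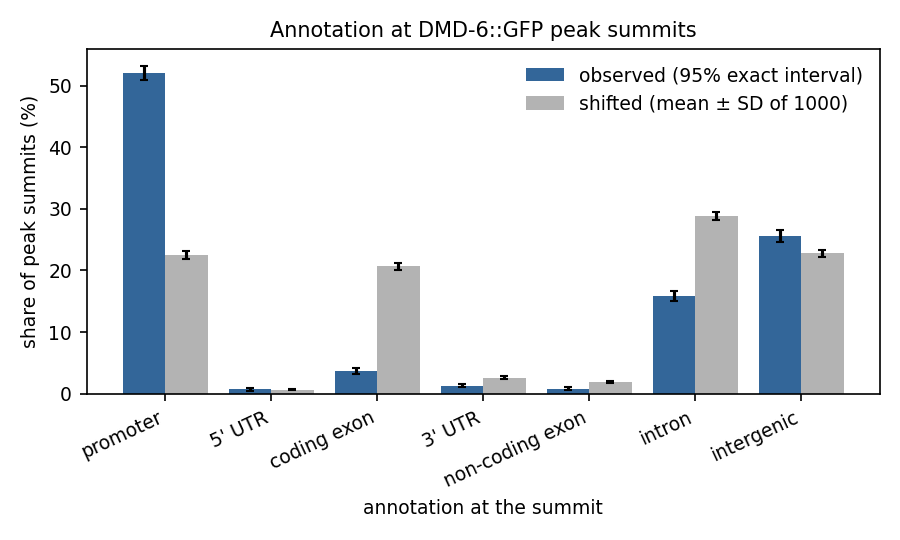
Bars give the share of the 7338 peak summits (y axis, percent) at each kind of annotated sequence (x axis), observed in blue with 95% exact binomial intervals and after circular shifts in grey as mean ± SD of 1000 shifts. Promoters held 52.1% of the summits against 22.5% after shifting, and coding exons 3.67% against 20.7%.

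The tagged gene itself carried peaks. Coordinates are 1-based on WBcel235, the assembly that the files call ce11. dmd-6 lies on the plus strand of chromosome IV from 14616603 to 14623963. Inside it were 3 peaks, all overlapping peaks of both replicates: IV from 14620240 to 14620413, in an intron, with a signal of 199.8 (rank 2324 of 7338); IV from 14617496 to 14617839, between annotated exons and beside a piRNA gene, with a signal of 158.5; and IV from 14620633 to 14620976, in an intron, with a signal of 138.1. No summit lay from 1000 bp upstream to 200 bp downstream of any annotated dmd-6 start site. Upstream of the gene, in sequence with no other protein-coding gene, 9 further peaks lay within 30 kb. They included the strongest peak of the main list, on IV from 14594153 to 14594753, with a signal of 1634 in the main list, 922.8 in replicate 1 and 682.7 in replicate 2. Its summit was 22.1 kb upstream of the annotated start of dmd-6. The nearest protein-coding start site was that of irld-18, 13432 bp away on the other side, and the summit lay in the promoter window of a piRNA gene, 21ur-865, 358 bp from its start, so the peak cannot be assigned to dmd-6 by distance.

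**Figure D3:**
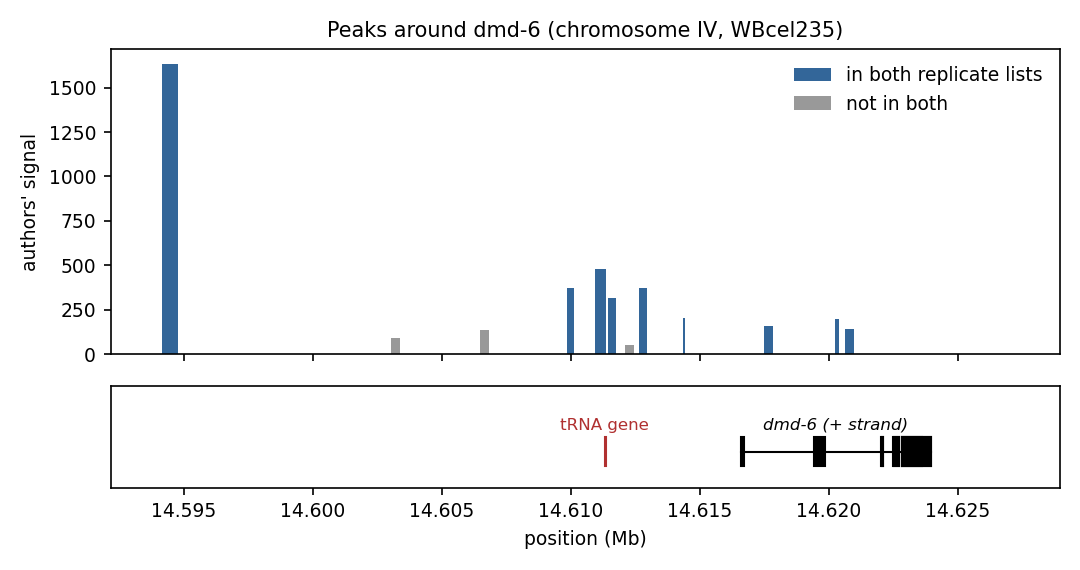
The map shows chromosome IV around dmd-6 (x axis, position in Mb on WBcel235), with each peak of the main list as a bar as wide as the peak and as high as the authors' signal (upper y axis), blue where both replicates held an overlapping peak and grey where they did not; the lower track shows the exons of dmd-6 as boxes and a tRNA gene in red. The strongest peak, with a signal of 1634, lies 22.1 kb upstream of the gene, and the 3 peaks inside the gene have signals from 138.1 to 199.8.

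Among the 10 DM-domain genes, 4 besides dmd-6 had a peak in the gene or within 2 kb of it. No share over other genes is given here for that window. dmd-7 had 5, of which the strongest, on chromosome V from 6246466 to 6246901 in the promoter, reached a signal of 874.8 (rank 40). dmd-8 had 2 intergenic peaks, both downstream of the gene, the stronger on V from 333753 to 334034 with a signal of 535.0. mab-3, which acts in male tail and intestine development, had a promoter peak on II from 9731773 to 9732116 with a signal of 166.7. It also had an intergenic peak downstream of the gene, from 9738887 to 9739170, with a signal of 401.0. dmd-5 had 1, on II from 5772823 to 5773166, with a signal of 161.0. No peak lay within 2 kb of dmd-3, dmd-4, dmd-9, dmd-10 or mab-23. With the gene window used for the lists below, dmd-7 and mab-3 had a peak, a share of 20% against 19.1% of other genes (Fisher's exact test, adjusted exact p = 1).

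The 15 strongest peaks that both replicates held had signals from 1166 to 1634. The protein-coding genes nearest to those in a gene window were rpl-3, which encodes a protein of the large ribosomal subunit (III from 3867420 to 3867726, signal 1632), H12C20.7, which shares its peak with nhr-68 (V from 11572824 to 11573331, signal 1466), tag-340, which shares its peak with nhl-2 (III from 4899692 to 4900103, signal 1382), mog-4, an RNA helicase of the hermaphrodite germline (II from 14561718 to 14562027, signal 1330), tasp-1, which shares its peak with K01G5.10 (III from 10759092 to 10759443, signal 1268), serp-1.1 (X from 15841115 to 15841433, signal 1234), cdc-48.1, a protein-unfolding ATPase (II from 10563430 to 10563705, signal 1193), and rpl-15, another ribosomal protein gene, which shares its peak with K11H12.8 (IV from 654782 to 655055, signal 1172). The other 7 had no protein-coding gene in that window. Besides the peak upstream of dmd-6, they lay in introns on X from 3290034 to 3290529 (signal 1423), on III from 12612447 to 12612902 (signal 1257) and on III from 1926441 to 1926805 (signal 1177), in intergenic sequence on III from 4281897 to 4282615 (signal 1239) and on II from 2973887 to 2974327 (signal 1171), and beside a piRNA gene on IV from 16180670 to 16181285 (signal 1166).

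The peaks were denser on X than on the autosomes. X held 1717 peaks, 23.4% of the list (exact interval 22.4 to 24.4%) on 17.7% of the sequence, or 96.9 per Mb, which is 1.32 times the number its length would give. Chromosome I held 0.817 times and chromosome IV 0.837 times the number by length, and II, III and V lay between 0.925 and 1.056 times (chi-square test over 6 chromosomes, p = 7.2e-46). Of the protein-coding genes on X, 24.9% (681 of 2731) had a peak, against 18.2% (3142 of 17242) on the autosomes (odds ratio 1.49, Fisher's exact test, p = 7.9e-16). On the autosomes, 43.3% of the peaks (2435 of 5621; exact interval 42.02 to 44.6%) lay in the central part of the chromosome that makes up 33.3% of its length (binomial test, p = 1.55e-54). The excess on X was lower, at 1.26 times, without the 344 summits within 200 bp of a tRNA gene, a choice made after seeing the data.

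The next comparison asked which kinds of genes had a peak from 1000 bp upstream to 200 bp downstream of a start site. Of 19973 protein-coding genes, 3823 (19.1%) did. Of 31 gene lists fixed before the data were examined, 5 had a peak more often than other genes and 6 less often (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). Genes that share a peak between them, as at divergent promoters, are not independent, and 685 of the 3801 assigned peaks had more than 1 gene.

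Genes of the intestine had peaks most often. Of 42 intestinal genes, 31 (73.8%) had a peak against 19.03% of other genes (log2 odds ratio 3.54 ± 0.50 SE, adjusted exact p = 2.4e-13). The members with the strongest peaks were vit-3 (X from 3572518 to 3572839, signal 554.7) and vit-6 (IV from 8260820 to 8261205, signal 480.1), which encode yolk proteins, and cpr-4 (V from 6614385 to 6614709, signal 542.4) and cpr-3 (V from 15298674 to 15298932, signal 509.3), which encode cathepsin B-like proteases. Of the other tissue lists, that of pan-neuronal genes passed (given separately) and these did not: body wall muscle 11 of 42, germline 8 of 71, hypodermis and seam 5 of 47, pharynx 2 of 35, excretory system and glia 5 of 31, and gonad, vulva and uterine development 5 of 39 (adjusted exact p from 0.097 to 0.88). Against the 10563 genes with a peak in any ranked list, the pharynx list passed as lower (adjusted exact p = 0.045).

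Cytosolic ribosomal protein genes followed, with 52 of 80 (65.0%, log2 odds ratio 2.98 ± 0.34 SE, adjusted exact p = 5.0e-18). Besides rpl-3 and rpl-15 they included rpl-20 (IV from 4749938 to 4750211, signal 1137), which shares its peak with Y17G9B.5, and rpl-35 (III from 7854557 to 7854821, signal 967.2). The number depends on how peaks are assigned: with each peak given to the nearest start site within 2000 bp, 29 of 80 had one (log2 odds ratio 1.19, adjusted exact p = 0.0022), and against genes with a peak in any ranked list the log2 odds ratio was 1.87. The genes of the mitochondrial ribosome (16 of 66, adjusted exact p = 0.37) and of the proteasome (8 of 33, adjusted exact p = 0.63) did not pass the test.

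Among detoxification enzymes, which modify foreign and lipid-soluble compounds, 75 of 185 (40.5%) had a peak (log2 odds ratio 1.55 ± 0.22 SE, adjusted exact p = 1.0e-10). The strongest were at the glucuronosyltransferase genes ugt-64 (V from 3505815 to 3506092, signal 689.5), ugt-20 (signal 623.1) and ugt-49 (signal 507.5) and at the glutathione transferase gene gst-42 (signal 486.6), which shares its peak with D1053.2. Among the 1000 strongest peaks alone the list no longer passed (adjusted exact p = 0.62). Of the nuclear hormone receptor genes, a large family of transcription factors in worms, 90 of 274 (32.8%) had a peak (log2 odds ratio 1.07 ± 0.19 SE, adjusted exact p = 4.0e-07). They were led by nhr-68 (signal 1466), which shares its peak with H12C20.7, nhr-35 (X from 4532114 to 4532602, signal 917.0), nhr-57 (signal 606.7) and nhr-58 (signal 601.7).

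Pan-neuronal genes also passed, with 12 of 26 (46.2%, log2 odds ratio 1.87 ± 0.56 SE, adjusted exact p = 0.0049), but on weak peaks and in neither replicate alone. The members with the strongest peaks were unc-11 (signal 168.1), syd-2 (signal 155.4), egl-21 (signal 150.6) and unc-76 (signal 115.6), which act in synaptic vesicle recycling, synapse assembly, neuropeptide processing and axon growth. In the list of replicate 2 alone 5 of the 26 had a peak (adjusted exact p = 0.58), in that of replicate 1 alone 6 (adjusted exact p = 0.54), and in the conservative list 9 (adjusted exact p = 0.070). Among the peaks found in both replicates 4 did (adjusted exact p = 0.70) and among the 1000 strongest 0 did, and against the 10563 genes with a peak in any ranked list the adjusted exact p was 0.25. The list passed with the window from 500 bp upstream to 100 bp downstream (9 of 26, adjusted exact p = 0.027), without summits near tRNA genes (adjusted exact p = 0.0040) and, with a higher log2 odds ratio of 2.65, with peaks given to the nearest start site (16 of 26, adjusted exact p = 2.8e-05).

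Chemoreceptor genes, which are expressed mostly in single sensory neurons, were nearly devoid of peaks: 36 of 1309 (2.75%) had one, against 20.3% of other genes (log2 odds ratio -3.15 ± 0.24 SE, adjusted exact p = 3.8e-75). Most of these genes had no peak in any ranked list either; among the 201 that did, 36 (17.9%) had a peak, against 36.5% of other such genes (log2 odds ratio -1.39, adjusted exact p = 1.9e-07). The strongest peaks were at srz-62 (signal 764.0), srh-2 (signal 665.8) and srh-70, which shares its peak with ceh-99 (signal 614.0). Neuropeptide and insulin-like peptide genes (10 of 145, 6.90%, adjusted exact p = 0.00024), cuticle collagen genes (15 of 175, 8.57%, adjusted exact p = 0.00057), F-box genes (36 of 322, 11.2%, adjusted exact p = 0.00057), hedgehog-related genes (5 of 85, 5.88%, adjusted exact p = 0.0027) and sperm protein genes (5 of 75, 6.67%, adjusted exact p = 0.013) also had peaks less often. Their strongest members were ins-7, which shares its peak with ZK1251.3 (signal 438.7), col-74 (signal 232.5), fbxc-29 (signal 688.5), ptc-1 (signal 220.9) and spe-54 (signal 323.9). Without replicate 1 the neuropeptide (6 of 145) and F-box (21 of 322) lists still passed (adjusted exact p = 0.0021 and 0.0011). Fewer of their genes had a peak there, but so did fewer other genes (13.1% for both comparisons). The log2 odds ratios were -1.69 and -1.08, against -1.62 and -0.906 in the main list. Without replicate 1, the hedgehog-related and sperm protein lists did not pass (adjusted exact p = 0.13 for both), nor did they among the peaks found in both replicates (4 of 85, adjusted exact p = 0.10, and 3 of 75, 0.087). Among the 1000 strongest peaks these lists and those of neuropeptides and F-box genes did not pass (adjusted exact p from 0.43 to 0.91), and the F-box list did not pass against genes with a peak in any ranked list (adjusted exact p = 0.23). The F-box shortfall was also uneven between families, a comparison chosen after the data were seen (Fisher's exact test, adjusted over all families tested). Of fbxb genes 1.92% had a peak (adjusted exact p = 2.7e-06) and of fbxc genes 6.25% (0.084). The largest F-box family, fbxa, did not differ from other genes, with 18.2% against 19.1% (adjusted exact p = 0.92).

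Of the lists that did not pass, homeobox genes (9 of 92) and neurotransmitter identity genes (0 of 20) had the lowest adjusted exact p, 0.055 for both, and lay below other genes, while the heterochronic genes of larval timing (5 of 10, adjusted exact p = 0.057), genes of Wnt and TGF-beta signalling (14 of 41, adjusted exact p = 0.057) and heat shock protein genes (8 of 22, adjusted exact p = 0.098) lay above. Several of these calls turn on a choice. Of single libraries, without replicate 1 the heterochronic genes passed (adjusted exact p = 0.018), and without replicate 2 the heat shock protein genes (adjusted exact p = 0.0086) and those of the cell cycle (adjusted exact p = 0.020) passed. In the conservative list the homeobox, heterochronic (adjusted exact p = 0.047 for both) and heat shock protein genes (adjusted exact p = 0.026) passed. Among the peaks found in both replicates, the heterochronic (adjusted exact p = 0.013) and heat shock protein genes (0.036) passed, and among the 1000 strongest peaks the heat shock protein genes (5 of 22, log2 odds ratio 3.27, adjusted exact p = 0.0039). With peaks given to the nearest start site, the homeobox (adjusted exact p = 0.0088), heterochronic (0.00031), Wnt and TGF-beta (0.0019) and heat shock protein genes (0.0042) passed, while 3 of 20 neurotransmitter identity genes then had a peak (0.87). With the window from 500 bp upstream to 100 bp downstream, the homeobox (adjusted exact p = 0.0026) and Wnt and TGF-beta genes (0.038) passed. Against genes with a peak in any ranked list, the homeobox and neurotransmitter identity genes passed (adjusted exact p = 0.030 for both). Without summits near tRNA genes, a choice made after seeing the data, the homeobox (adjusted exact p = 0.012), Wnt and TGF-beta (0.038) and neurotransmitter identity genes (0.049) passed. The remaining lists were cell cycle and DNA replication (13 of 42, adjusted exact p = 0.13), the insulin and dauer pathway (7 of 22), sex determination and dosage compensation (6 of 25), bHLH genes (7 of 39), histones (12 of 72) and C-type lectins (44 of 240), with adjusted exact p from 0.26 to 1. The members of these lists with the strongest peaks were mog-4, hsp-3 (signal 895.9), mdl-1 (signal 779.5), his-37 (signal 732.1), clec-50 (signal 506.3), tig-3 (signal 462.7), lin-46 (signal 455.5), pcn-1 (signal 444.5) and daf-16 (signal 351.1).

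**Figure D4:**
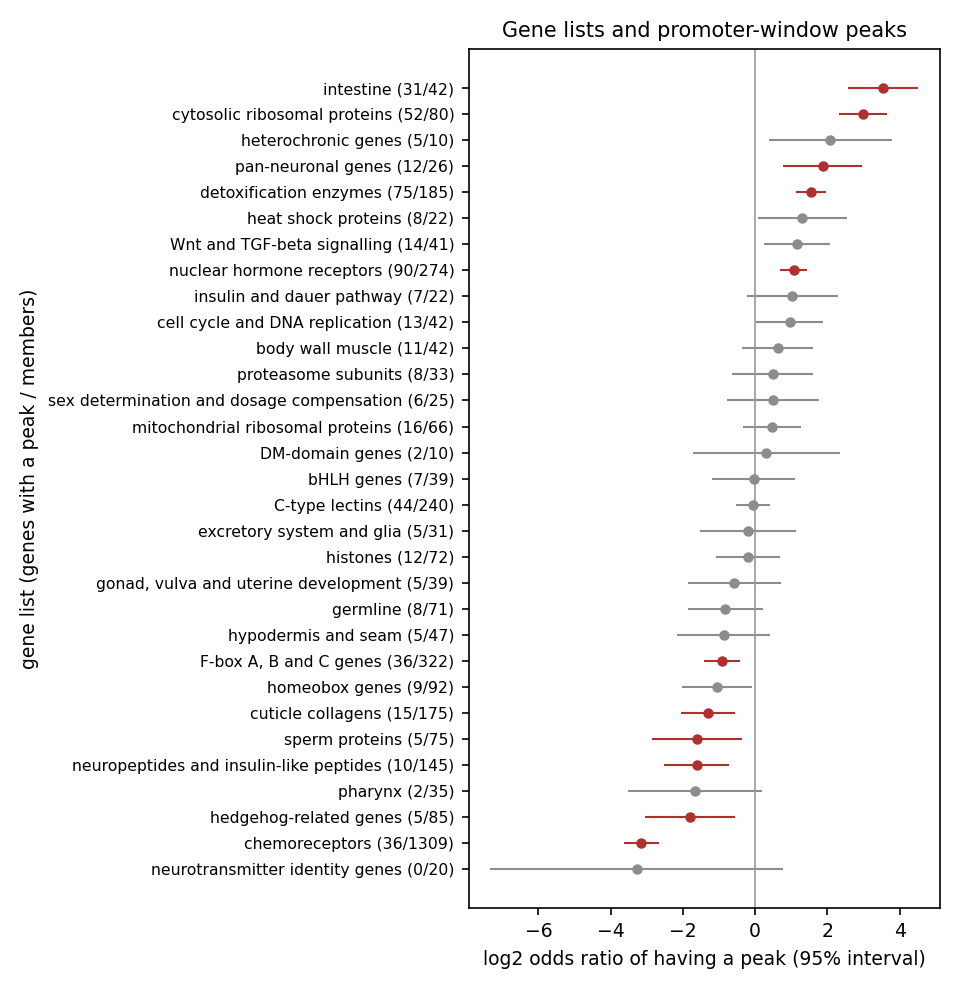
Points give the log2 odds ratio (x axis) of having a promoter-window peak for each of the 31 gene lists (y axis, with genes with a peak and members in brackets), and lines the 95% intervals, in red where the adjusted p was under 0.05. The intestine (31 of 42) and cytosolic ribosomal proteins (52 of 80) stand highest and the chemoreceptors (36 of 1309) are among the lowest.

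Sequence words fixed before the data were examined were counted within 50 bp of each summit and in windows of the same width centred 350 bp to the left. The word bound by GATA factors, which include the regulators of intestinal genes, stood out most. TGATAAG was in 16.7% of the summit windows (1223 of 7338) against 1.65% of the control windows, a ratio of 10.1 (exact McNemar test, adjusted exact p = 1.0e-237), and the ratio was 15.2 in the fifth of peaks with the highest signal and 5.17 in the fifth with the lowest. The GAGA repeat GAGAGA was in 19.4% against 5.57% (ratio 3.49), the E-box CACGTG, bound by Myc-type bHLH proteins, in 6.88% against 1.65% (ratio 4.17), the GC box GGGCGG in 4.28% against 1.43%, the E2F word TTSGCGC in 3.28% against 1.36%, the Sp1/KLF word GGTGTG in 4.77% against 2.33% and the E-box CAGCTG in 3.35% against 1.79% (adjusted exact p from 7.1e-146 to 3.5e-09). The AP-1 word TGASTCA (ratio 1.84, adjusted exact p = 7.2e-05) and the nuclear receptor word AGGTCA (ratio 1.397, adjusted exact p = 0.00066) were also more frequent, but not in every setting. The AP-1 word did not pass without replicate 1 (ratio 1.375, adjusted exact p = 0.14), within 25 bp of the summit (0.14) or among the 1000 strongest peaks (0.056), and the nuclear receptor word did not pass among the 1000 strongest peaks (ratio 1.27, adjusted exact p = 0.50) or at promoter summits (ratio 1.27, 0.10). TATAAA (6.41% against 12.5%) and TAATTA (2.07% against 5.53%) were less frequent.

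The words known for DM-domain proteins were not found enriched at the summits. The DM core ACAWTGT was in 1.87% of the summit windows and 1.91% of the control windows (ratio 0.979, exact McNemar test, adjusted exact p = 0.90), and the MAB-3-type word ATGTTGC in 1.59% against 1.44% (ratio 1.104, adjusted exact p = 0.57). In the fifth of peaks with the highest signal, the ratios were 1.25 (adjusted exact p = 0.53) and 1.63 (adjusted exact p = 0.16). In simulated data, the DM word was called when planted in 1% of 7338 windows at random genome positions. The genome holds 35.4% G and C, against 42.5% in the real summit windows, so the simulation does not give the power at the real summits. The words TTTCTT, TGTTTAC and GTTACC did not pass against the left control windows (adjusted exact p from 0.056 to 0.57). TGTTTAC, a forkhead word, passed against the right control windows (ratio 1.505, adjusted exact p = 0.0019), in the conservative list, within 25 bp of the summit and at promoter summits (adjusted exact p from 0.016 to 0.029). GTTACC passed as less frequent in the conservative list (adjusted exact p = 0.0069) and in peaks found in both replicates (0.023). Summit windows were richer in G and C (42.5%) than the left (34.7%) and right (34.5%) control windows. Set against shuffled copies of the summit windows with the same dinucleotides, TATAAA (ratio 1.34, adjusted exact p = 3.4e-05) and TTTCTT (ratio 1.26, 7.1e-12) were more frequent, GTTACC was less frequent (ratio 0.653, 0.0017), and the AP-1 word (ratio 1.04, adjusted exact p = 0.85) and the nuclear receptor word (ratio 0.955, adjusted exact p = 0.71) no longer passed. The ratios of GAGAGA (2.03), GGTGTG (1.21) and TAATTA (0.688) lay nearer to 1 against these copies and still passed (adjusted exact p up to 0.020). The same held for CACGTG (3.39), GGGCGG (2.18), CAGCTG (1.78) and TTSGCGC (1.73), while the ratio of TGATAAG was higher (14.4).

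**Figure D5:**
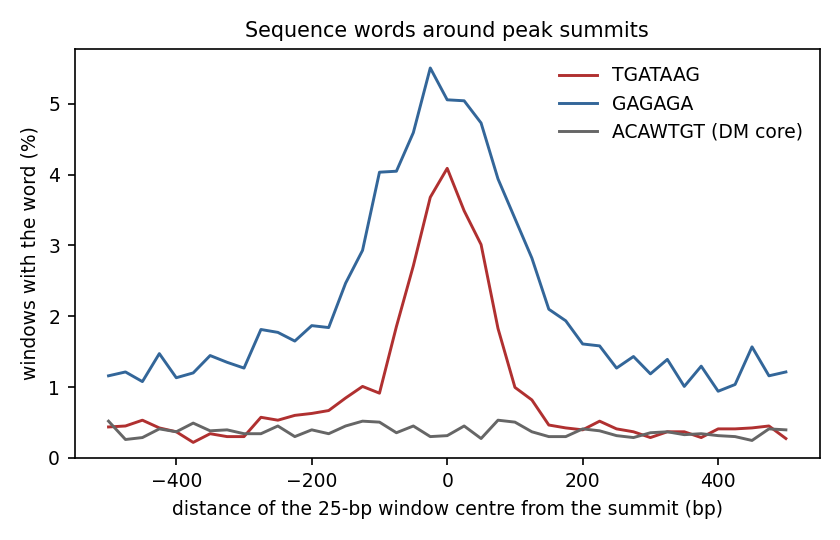
Lines give the share of 25-bp windows that held a word (y axis, percent) by the distance of the window centre from the summit (x axis, bp) over the 7338 peaks of the main list. TGATAAG rises from 0.341% at 350 bp to the left to 4.09% at the summit and GAGAGA from 1.44% to 5.06%, while the DM core stays near its flank level, at 0.382% and 0.313%.

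A search over all words of 7 bases also put the GATA word first. On chromosomes I, II and III (3134 peaks), 1770 words were more frequent at summits than in both flanks (one-sided Fisher's exact test, adjusted p under 0.05). The 10 with the smallest p were then tested on IV, V and X (4204 peaks), where all 10 passed. Summit windows are richer in G and C than the flanks, and no shuffled windows were used in this search. Passing on IV, V and X therefore does not by itself set a word apart from base composition. CTTATCA, the reverse complement of the GATA word, came first, in 17.3% of the summit windows against 1.65% of the flanks on the test chromosomes (ratio 10.5, adjusted exact p = 4.5e-223), and GATAAGA, CTGATAA and ACTGATA overlap it. CTCTCTC, AGAGAGA and GAGAGAC hold the GAGA repeat (ratios 5.51, 3.96 and 5.65), and ACGCAGA, CTGCGTC and AGAGACG (ratios 7, 7.70 and 6.95) contain none of the 16 fixed words. With the middle word read as its reverse complement, these last words share ends with each other. They also share an end with the repeat-holding word of ratio 5.65. They may therefore be parts of a longer sequence, to which some of the repeat signal may belong. This was not tested.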

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

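The test of the DM word in the strongest peaks was chosen after its result was seen; the other tests in this part had bounds written before their results were seen. One signal lies outside the lists compared above: 45 peaks of the ranked list for both replicates passed the IDR threshold and are not in the thresholded list. They include the strongest peak of that ranked list, on X from 15810936 to 15811188 with a signal of 1781, and 39 of the 45 overlap an entry of both replicates' ranked lists. 42 of the 45 summits lie outside annotated genes.

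The first pattern is that peak summits were rich in the GATA word and not in words for a DM-domain protein. Base composition is argued against, since TGATAAG was 14.4 times as frequent in the summit windows as in shuffled windows with the same dinucleotides (16.7% against 1.16%). The second test took the 3801 summits in the gene window of a protein-coding gene (from 1000 bp upstream to 200 bp downstream). TGATAAG was 8.86 times as frequent there as at the same distance from start sites of genes without a peak (16.8% against 1.89%). Distance from a start site alone is thus argued against. A general property of active or accessible promoters cannot be told apart, since the comparison genes were chosen for having no peak. The missing DM core is not explained by composition, as ACAWTGT was 0.797 times as frequent as in shuffled windows (1.87% against 2.34%). Dilution by weak peaks cannot be told apart from absence, as its ratio of 1.25 in the 1468 strongest peaks has an exact 95% interval of 0.706 to 2.23. The MAB-3-type word ATGTTGC was in 1.59% of both summit and shuffled windows. Its ratio to the left control windows in the 1468 strongest peaks was 1.63 (31 against 19 windows, exact McNemar test, adjusted exact p = 0.16). In the 1000 strongest it was 1.77 (0.18). Over the same 5 groups, from strongest to weakest, it was 1.63, 1, 1.37, 1.63 and 0.357. It was lowest in the weakest group but did not fall steadily with signal. No interval was computed for this word, so dilution remains open for it too. Recruitment by other factors, open chromatin in the intestine that many proteins share, a different DMD-6 site, and signal of the tag or antibody that does not need DMD-6 all remain open, since no untagged strain, accessibility map or other factor was analysed here. No biological explanation was tested, as the design has 1 group.

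The second pattern is that 368 of 612 tRNA genes (60.1%) had a summit from 500 bp upstream to 100 bp downstream, against 15% of protein-coding genes. Neighbouring coding promoters are argued against, since 58.3% (222 of 381; exact interval 53.1 to 63.3%) of the tRNA genes more than 1000 bp from every coding start site had one. Reads shared between identical copies cannot be told apart from other causes: tRNA genes of unique sequence had a peak 0.665 times as often as repeated ones (43.4% of 143 against 65.2% of 469; 95% interval of the ratio 0.545 to 0.811), between the bounds set for the test, and unique copies may also be less transcribed. The tRNA peaks rarely held the GATA word (2.96%). Chromatin that precipitates easily at strongly transcribed genes remains open, and no biological explanation was tested.

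The third pattern is the excess of X-linked genes with a peak (odds ratio 1.49). The many autosomal chemoreceptor, F-box and C-type lectin genes are argued against as its whole cause, since without them the odds ratio was 1.38 (95% interval 1.25 to 1.52; 25.24% against 19.7%). The longer space upstream of X genes (median 2123 bp against 826 bp) is argued against too, with an odds ratio of 1.54 (1.34 to 1.75) among genes with at least 1500 bp free of coding genes upstream. X also holds 276 tRNA genes, of which 64.1% had a peak, against 336 on all autosomes, of which 56.8% did. The odds ratio was not computed without summits near tRNA genes, so their part in it is unknown. Differences in mappability and in accessible chromatin remain open, as does a biological preference, which was not tested.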

How the results depend on the processing

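Peaks in both replicates and peaks away from tRNA genes were used as alternatives only after the data were seen; the others were planned. Of 50 alternative values for the main results, 48 kept their direction and side of the threshold, or a count within 1.5 times. The number of gene lists past the threshold fell from 11 to 6 with the 1000 strongest peaks, which leaves fewer genes with a peak, and was 9 to 15 otherwise. Spearman's rho was 0.813 over the 14673 pairs of the ranked lists, below the interval of the main value; the cause was not tested. Each replicate alone gave a promoter share of 53.9% to 54.2% and 1.303 to 1.35 times the number of peaks on X by length. Over all alternatives the promoter share was 39.2% to 65.9%, at 1.73 to 2.79 times the shifted level, and the overlap 50.6% to 97.7%. Among 446 values of single lists, words and the chromosome centre, 393 stayed on their side of the threshold without a call reversing. With the direction kept, 29 passed only in the alternative and 21 only in the main analysis. The other 3 changed direction: the log2 odds ratio of pan-neuronal genes was -0.80 among the 1000 strongest peaks, where 0 of 26 had one, and the ratio to shuffled windows was 1.34 for TATAAA and 0.955 for AGGTCA. A changed direction need not be a call the other way: TATAAA passed against shuffled windows, but AGGTCA did not (exact McNemar test, adjusted exact p = 0.71). The 393 include 40 values that passed neither in the main analysis nor in the alternative and changed sign. The cause was not tested, though shuffling keeps the base composition that differs from the flanks. Of the leading 7-mers, 7 to 10 remained among the leading 10. With unknown read depth, the difference in peak number between replicates cannot be set against sequencing yield. No paired analysis was possible because there is 1 group.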

Other observations

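These comparisons were chosen after the data were seen. Of 175 gene families with at least 10 protein-coding members, taken from the gene names, 19 had peaks more often and 20 less often than other genes (Fisher's exact test, Benjamini-Hochberg over the families), and 8 of the 19 shared no member with the fixed lists. Among the latter were bZIP transcription factors named zip (9 of 12, adjusted exact p = 0.00058, led by zip-2), galectins (8 of 12, adjusted exact p = 0.0039, led by lec-9), acyltransferases of lipid synthesis (acl, 8 of 13, adjusted exact p = 0.0073, led by acl-6), acyl-CoA synthetases (acs, 11 of 22, adjusted exact p = 0.0079, led by acs-14) and short-chain dehydrogenases (dhs, 13 of 30, adjusted exact p = 0.013, led by dhs-25), with the remaining families being vps (13 of 31), alh (7 of 13) and npp (11 of 26). Vacuolar ATPase genes (vha) reached 11 of 20 (adjusted exact p = 0.0037). Ligand-gated channel genes of the lgc family had a peak in 2 of 56 (adjusted exact p = 0.0079) and irld genes in 1 of 56 (adjusted exact p = 0.0024).

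The GATA word was compared between the summits of each of the 5 lists with more peaks and the other gene-window summits. TGATAAG was within 50 bp of 0 of 53 summits at cytosolic ribosomal protein genes (exact 95% interval up to 6.72%), against 17.02% of the other gene-window summits (Fisher's exact test, adjusted exact p = 0.00056 over 5 lists). At pan-neuronal genes it was at 0 of 14 summits (exact 95% interval up to 23.2%, adjusted exact p = 0.24). At intestinal genes it was at 11 of 38 summits (28.9%, adjusted exact p = 0.13), and at detoxification and nuclear hormone receptor genes at 20% and 16.04% (adjusted exact p = 0.58 and 1).

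Among genes that do not encode proteins, a summit lay in the promoter window of 105 of 346 snoRNA genes (30.3%), of 27.9% of snRNA genes and of 189 of 15363 piRNA genes (1.23%). The sequence around dmd-6 was dense in peaks: 12 lay from 30 kb upstream to 5 kb downstream, 0.283 per kb against a median of 0.0551 per kb over all protein-coding genes in the same window, and 1.47% of them had at least that density.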
